A study of Oryza sativa with 3 samples.

How the data were processed

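Total RNA from roots of 6-day-old rice seedlings (Oryza sativa, cultivar TN-67) was compared between seedlings exposed to 1 mM vanadium and seedlings exposed to water. Per the labels' protocols, RNA was amplified to cRNA, the vanadium samples were labelled with Cy5 (red) and the water controls with Cy3 (green). Each of 3 arrays held the treated and the control RNA of the same replicate number, and the labels call the replicates biological. The dyes were not swapped on any array, so a gene-specific dye effect and the treatment have the same sign everywhere.

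The deposited array files hold spot and local background intensity in both channels as the scanner software read it, without normalization. Per the file headers, they were made with Agilent Feature Extraction 10.7.1.1. The same deposited files hold a processed intensity, background-subtracted and dye-normalized by that software, and a log10 ratio of red over green made from it. The authors' deposited value table holds log2 ratios. Set against the array files, it equalled log2 of red over green processed intensity for 100% of 41882 probes with a single spot, within a tolerance of 0.001, so its scale and direction were settled. Its columns had medians of -0.05, -0.19 and -0.21 for replicates 1, 2 and 3, so it was not centred on the median. The steps that led from RNA to scanner settings beyond these are not given in the sources used here.

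The median signals were used, since the columns at hand gave medians and the fit had been planned on mean signals. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0 (limma 3.58.1 in R 4.3.3). Spots marked as outliers by the scanner software were left out, which concerned 1090, 401 and 306 of 45151 spots on replicates 1, 2 and 3, and no spot was saturated. Spots of one probe were averaged. A probe was kept if it was well above background in red on all 3 arrays or in green on all 3 arrays. Of the probes kept for a locus, the brightest was used. This left 21095 of 29689 loci, and 8594 had no probe that was kept. Among 5702 loci with several probes kept, 2421 had at least 2 probes past the threshold, and on 100 of all these loci probes were called in opposite directions.

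The mean log2 ratio of vanadium over water was tested against 0 with limma's moderated test (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) are those of this test, which draws the variance of each locus toward a value shared by all loci. At uneven loci they are therefore smaller than the spread of the 3 arrays alone would give. The treated and control RNA of a replicate share an array, which is where the pairing comes from. Deviations of red and green from their means over arrays correlated across genes at 0.765, 0.606 and 0.773 within replicates 1, 2 and 3, and at most at 0.0354 between channels of different arrays. Subtracting means over 3 arrays forces the values between arrays down, and spot effects shared by both channels can raise those within an array. The contrast therefore does not measure how strong the pairing of the RNAs was. A fit of the channels without this pairing was run as an alternative. Replicate 1 lay on slide 1 and replicates 2 and 3 on slide 2, each scanned with its own slide, and every slide held both treatments.

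On simulated intensities for the real spots with 200 loci changed, the same steps recovered 47.8% of 67 loci changed 1.5-fold, 95.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, among 21095 loci tested. Of 168 calls there, 6 were false (3.57%). The simulated changes were few, drawn evenly in both directions and independent between loci, with no gene-specific dye effect. In the data 10766 loci were called, with 1870 higher and 333 lower at 2-fold or more. The share of false calls among them is therefore not given by this simulation. With 3 arrays, their number limits the precision.

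The array files identify loci by rice locus number and do not pair them with gene names or descriptions. The reference table used here (assembly ASM3414082v1) gives symbols without these locus numbers. The rule for named genes, the 10 largest rises and 10 largest falls with a symbol or description, therefore named none, and gene symbols are not printed. The description patterns of 43 planned lists could not be applied. Gene groups rest on locus numbers written from general knowledge: 47 fixed before the data were examined and 167 written afterwards. The later ones were written before the fit was run but after single ratios had been seen. Each ratio is itself vanadium over water, so an influence of the values on the choice of these lists is not excluded. As a check, the symbol recalled for a locus was looked up in the reference table, and 179 of 184 symbols found on the chromosome in the locus number also followed its order. Shuffled positions gave at most 75 of 184 in 1000 shuffles. Written afterwards, a locus was used only if it passed this check (142 of 167), while all 47 fixed loci were used, of which 37 passed. The check does not prove that any single locus has the function of its list.

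Lists with at least 5 tested loci were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the lists of the same origin. Camera compares a list with the other genes, while fry tests whether its loci move one way and makes no such comparison. Alternatives covered background correction, normalization, the filter on dim probes, several probes per locus, the variance model, the pairing, the threshold and leaving out each array. Probes named after miRNAs were fitted apart by the same steps.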

Results

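Root transcripts of rice seedlings exposed to 1 mM vanadium, a transition metal, were compared with those of seedlings in water on 3 arrays, each carrying the treated and the control RNA of 1 biological replicate. The comparison addresses the response of the root to vanadium stress, which the series title calls early, and the labels give no exposure time. Between 31279 and 32245 of 41889 gene probes per array were well above background in the vanadium channel, and between 29260 and 31919 in the water channel. Negative control spots had median signals of 62, 67 and 68 in the vanadium channel on replicates 1, 2 and 3. In the water channel these were 89, 160 and 154.5. The channels differ in dye as well as treatment, so the counts of probes do not show that more genes were expressed under vanadium. Log2 ratios of the arrays correlated across genes at 0.901, 0.929 and 0.932, where genes are not independent replicates. With the dyes never swapped, a gene-specific dye effect would raise these correlations as well.

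Under vanadium, 6273 of 21095 tested loci were higher and 4493 were lower than in water (limma, adjusted p under 0.05, n = 3 arrays). Changes of at least 2-fold were found at 2203 loci, of which 1870 were higher and 333 were lower. At least 4-fold, 641 loci were higher and 11 lower, and 75 loci were at least 16-fold higher. The median standard error of a log2 ratio was 0.09. Of all 21095 tested loci, 15569 (73.8%) had the same sign on all 3 arrays, a share that a gene-specific dye effect would also raise. The split between directions depended on the scaling: 58.3% of changed loci were higher here, against 41.5% (4882 higher and 6882 lower) with the scanner software's own log ratio. That scaling moved the ratios by a median of -0.14 on the log2 scale, and 9205 loci were called in the same direction under both scalings and 2 in opposite directions. At 2-fold it gave 2454 higher and 1111 lower loci.

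**Figure D1:**
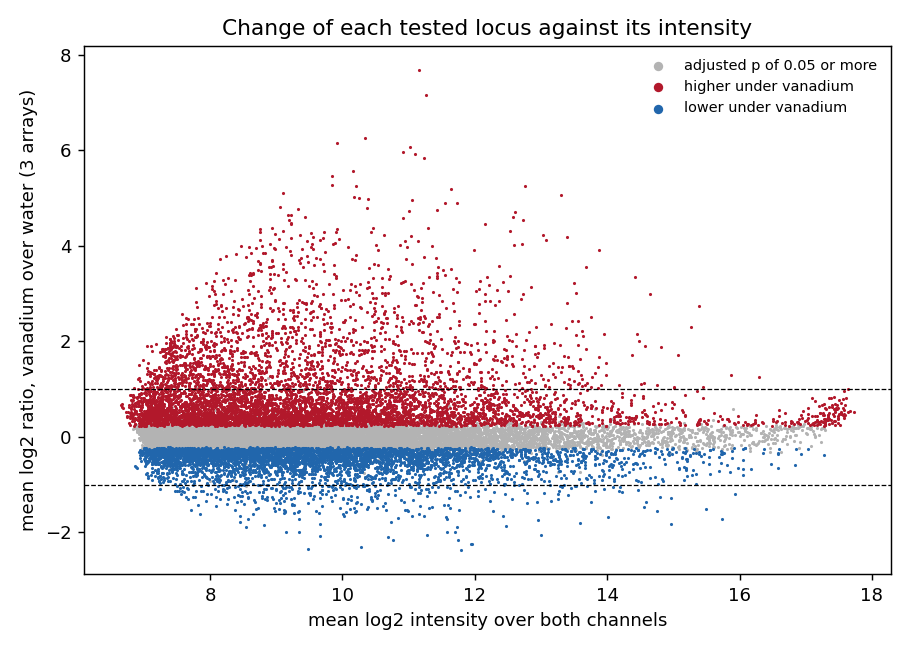
Mean log2 ratio of vanadium over water (vertical axis) against mean log2 intensity over both channels (horizontal axis) for each of 21095 tested loci, 1 point per locus, with dashed lines at 2-fold. Rises reached 7.68 and falls -2.37 on the log2 scale, and 1870 called loci lie on or above the upper line against 333 on or below the lower line.

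The files do not pair loci with names, so only the 2 largest changes each way are identified by locus number. Os04g0203600 was higher by 7.68 ± 0.12 (SE, n = 3 arrays) on the log2 scale, with its water channel well above background on 2 of 3 arrays. Os08g0177400 was higher by 7.16 ± 0.17. The largest falls were at Os07g0677300, with a log2 ratio of -2.37 ± 0.11, and at Os04g0515900, with -2.35 ± 0.15. All 4 were chosen among called loci with the same sign on every array, so neither trait adds support. Their adjusted p lay between 1.73e-06 and 6.18e-05 (limma).

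Loci listed for jasmonate synthesis and response, the hormone pathway of wounding and defence, rose together. All 12 tested loci were higher, with a median log2 ratio of 1.97. Adjustment over the list alone, where every locus already passes over all genes, must keep them all and adds no support. The 4 largest rises were 4.29 ± 0.10, 3.91 ± 0.20, 3.40 ± 0.09 and 2.85 ± 0.13 (SE, n = 3 arrays). The rises of 4.29, 3.91 and 2.85 were at loci adjacent in locus number, where cross-hybridisation was not tested. They may not be separate rises. The smallest rise was 0.25 ± 0.08, at a locus that did not pass the order check. Over the alternatives 9 to 12 were called. The median was 1.91, 1.85 and 2.13 on replicates 1, 2 and 3. The list stood above the other genes in camera (adjusted p = 3.20e-06), while its adjusted p = 0.350 with an estimated correlation. Over all alternatives with camera its adjusted p lay between 7.71e-10 and 0.350.

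Loci listed for iron acquisition and homeostasis, which include synthesis and transport of metal chelators, mostly fell. Of 9 tested loci 7 were lower and 2 did not pass the test, with a median log2 ratio of -0.76. For 3 of the 9 loci the vanadium channel was not well above background on at least 1 array. Adjusted over the list alone, 7 were lower and 1 was higher, and over the alternatives 4 to 7 were lower. The largest falls were -1.79 ± 0.27, -1.39 ± 0.33, -1.37 ± 0.10 and -0.99 ± 0.10 (SE, n = 3 arrays). The first 2 of these were uneven, with log2 ratios of -1.13, -2.67 and -1.57 at the first and -0.48, -2.42 and -1.27 at the second on replicates 1, 2 and 3. These 2 loci are neighbours in locus number. Cross-hybridisation between them was not tested, so they may not be separate falls. The locus at -0.99 did not pass the order check, and its vanadium channel was well above background on 2 of 3 arrays. Camera placed the list below the other genes (adjusted p = 0.00338), but adjusted p = 0.350 with an estimated correlation, 0.111 on probes well above background in both channels, and 0.0625 over the loci that passed the order check. Over all alternatives with camera the range was 0.000489 to 0.350.

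Of 6 loci listed for phosphate starvation, 3 were higher and 3 did not pass the test, both over all genes and adjusted over the list alone. The median log2 ratio was 0.22, and 0.06 to 0.29 over the alternatives. Over the alternatives 1 to 3 were higher and 0 to 1 lower, with 2 higher and 1 lower under the scanner log ratio. The list did not stand apart from other genes (camera, adjusted p = 0.388, and 0.248 to 0.711 over its alternatives). Tested with fry against no change, not against other genes, it had adjusted p = 0.0247.

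Other lists fixed before the data were examined had fewer than 5 tested loci and no set test. All 4 loci listed for abscisic acid and dehydration were higher, with a median log2 ratio of 1.75 and the largest rise at 2.78 ± 0.19 (SE, n = 3 arrays). For 1 of them, which did not pass the order check, the water channel was not well above background on any array. With a floor on its water signal it was 2.81-fold higher. That estimate sets the vanadium mean against the higher of the lowest signal above background and the probe's own, per channel. It leaves out the error of the mean, so it is not a strict lower bound, and it is open to dye bias. All 4 loci listed for fermentation and hypoxia were higher, the largest by 1.90 ± 0.10, and the rise of the second largest was 2.61, 1.15 and 1.06 on replicates 1, 2 and 3. The loci at 1.90 and 1.38 are close in locus number, and cross-hybridisation between them was not tested. Over the alternatives 2 to 4 of the fermentation loci were called, with 2 when channels were fitted without pairing. All 3 loci listed for ethylene were higher, the largest by 2.65 ± 0.15 and the smallest by 0.23 ± 0.08, and 1 to 3 of them were called over the alternatives. Adjusted over the list alone, the counts of these 3 lists were 4, 4 and 3. These counts were fixed, since every locus had passed over all genes. Of 3 loci of commonly used reference genes, 2 were higher, by 0.39 ± 0.08 and 0.30 ± 0.08, and 1 was lower, at -0.32. The same counts adjusted over the list alone were fixed in the same way. The locus at 0.39 did not pass the order check. With median centring 1 reference locus was higher and 0 lower, and without replicate 3 or without the pairing of channels none was called.

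Lists written after the data were opened gave further groups. Single ratios of vanadium over water had been seen by then. The tests of all lists not fixed beforehand may therefore not be independent of the choice of the lists. All 9 loci listed as ABC transporters of the PDR type, efflux pumps of the plasma membrane, were higher, with a median log2 ratio of 2.37 and rises up to 5.24 ± 0.12 (SE, n = 3 arrays). The 2 largest rises, 5.24 and 3.76, were at neighbours in locus number. Cross-hybridisation between them was not tested, so they may not be separate rises. At the next largest, 2.99, the water channel was not well above background on any array. For the PDR list camera gave adjusted p = 9.35e-06, against adjusted p = 0.374 with an estimated correlation, the highest of its alternatives, which began at 5.01e-09. All 5 loci listed as WRKY transcription factors, regulators of defence and stress genes, were higher, with a median of 2.98 and rises up to 4.32 ± 0.15. Of these loci 2 are close in locus number, and cross-hybridisation between them was not tested. The WRKY list had adjusted p = 0.000735, and alternatives ranged from 2.21e-06 to adjusted p = 0.374 with an estimated correlation. Of 9 loci listed as DREB and NAC stress factors, 6 were higher and 3 did not pass the test, with a median of 0.97 and adjusted p = 0.00795. The NAC loci were all higher, at 2.43, 2.05 and 1.86. All 3 loci that did not pass were DREB loci, at 0.45, 0.25 and -0.56, with signs that differed between arrays. Over the alternatives 5 to 8 of the 9 loci were higher and 0 to 1 lower. The adjusted p of the list ranged from 0.00110 to adjusted p = 0.608 with an estimated correlation. Adjusted over the list alone, 9, 5 and 6 loci of these lists were higher. For the first 2 lists that was fixed, since every locus had passed over all genes.

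Of 12 loci listed as aquaporins, membrane channels for water and small solutes, 10 were lower and 2 did not pass the test, with a median log2 ratio of -0.68 and the largest fall at -1.17 ± 0.10 (SE, n = 3 arrays). Adjusted over the list alone, 10 were lower and 1 was higher. Camera gave adjusted p = 0.000520, against adjusted p = 0.608 with an estimated correlation, the highest of its alternatives. Over the alternatives 6 to 11 loci were lower. The median was -0.92, -0.50 and -0.56 on replicates 1, 2 and 3.

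Of 14 loci listed for auxin response, 10 were higher, 2 were lower and 2 did not pass the test, with a median of 0.52, the same counts adjusted over the list alone, and the largest rises at 3.24 ± 0.16 and 2.74 ± 0.11 (SE, n = 3 arrays). Over the alternatives 7 to 10 were higher and 1 to 3 lower. Camera gave adjusted p = 0.0343. The call was lost without replicate 2 (adjusted p = 0.0627) and with an estimated correlation (adjusted p = 0.608), and the alternatives with camera began at 0.00839.

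Of 6 loci listed for diterpenoid phytoalexin synthesis, antimicrobial compounds of rice, 5 were higher, and the median was 1.86. These values depended on the filter for dim probes, since all 5 had a water channel that was not well above background on at least 1 array. On probes well above background in both channels 0 of 2 loci were called (median 0.40), and without the filter 4 of 10 were higher (median 0.37). The rise was uneven: the median was 3.39 on replicate 1, against 1.30 and 0.89 on replicates 2 and 3. The locus with the largest rise had a water channel that was not well above background on any array. That locus and those at 2.71 and 2.17 are adjacent in locus number among tested loci. Cross-hybridisation between them was not tested, so they may not be separate rises. The list itself was not called (camera, adjusted p = 0.106). It was called in 6 of 15 alternatives with camera: with slide as a block (adjusted p = 0.00126, a choice made after the data were seen), without replicate 3 (0.00528), with median centring (0.00561), with the scanner log ratio (0.0166), with the authors' table (0.0183) and without replicate 1 (0.0367, median 1.09). The others reached 0.657.

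The remaining lists with at least 5 tested loci were not called by camera in the main fit. Among 14 loci of heat shock proteins and heat stress factors 3 were higher, 2 lower and 9 not called, with a median of 0.05 (camera, adjusted p = 0.943) that was -0.08 with the scanner log ratio. Over the alternatives 0 to 4 were higher and 1 to 4 lower. Among 10 loci of metal and silicon transport 1 was higher and 4 were lower (adjusted p = 0.304), the largest fall reaching -2.06 ± 0.20 (SE, n = 3 arrays). Among 7 antioxidant enzyme loci 1 was higher (0 to 2 over the alternatives) and 2 were lower (1 to 2, adjusted p = 0.404), with a median of -0.12 that was 0.09 without the filter on dim probes. Tested with fry against no change, the antioxidant list was called (adjusted p = 0.00110). In that list 1 locus stood at -1.47 ± 0.11, while the others lay between -0.33 and 0.32. The call therefore does not show that these loci fell together. Of 6 type-A cytokinin response regulators 4 were higher and 1 was lower (adjusted p = 0.304), and 2 were higher with median centring and with the scanner log ratio, with 2 to 5 over the alternatives. Of 5 defence protein loci 3 were higher (adjusted p = 0.107), against 1 with the scanner log ratio and 1 to 5 over the alternatives. The defence list was called with median centring (adjusted p = 0.0239) and without the filter on dim probes (0.0401), and with fry against no change (0.0434). Of 5 loci for nitrogen and potassium uptake 1 was higher (0 to 2 over the alternatives) and 1 lower. The list had a median of 0.12, which was -0.06 to 0.18 over the alternatives. Its mean was -0.14, with the lowest locus at -1.65, and its test direction was downward (camera, adjusted p = 0.943).

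A further 4 lists had fewer than 5 tested loci and no set test. All 4 loci listed as calcium-dependent kinases were higher, with a median log2 ratio of 0.75 and the largest rise at 2.48 ± 0.08 (SE, n = 3 arrays), and 2 to 4 were called over the alternatives. The 1 locus listed for alternative respiration was higher by 3.98 ± 0.11, and under every alternative. Of 3 loci listed as MAP kinases 1 was higher, by 2.57 ± 0.12, with 1 to 2 over the alternatives. The 1 locus listed as a respiratory burst oxidase was lower, at -0.32 ± 0.08, and was not called in 4 of 16 alternatives.

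Relative to the median of all loci under the scanner log ratio, the list medians were 2.03 for jasmonate, -1.40 for iron, 2.78 for the PDR transporters, 4.08 for WRKY factors and -0.63 for aquaporins. With slide as a block they were 1.95, -0.75, 2.42, 2.81 and -0.76.

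Markers of other tissues were few. Of loci listed for photosynthesis, a sign of green shoot tissue, 2 were tested and 0 passed limma's threshold, with a median log2 ratio of -0.55 that was -1.57 on replicate 1, 0.04 on replicate 2 and -0.11 on replicate 3. Without replicate 3, and with slide as a block, 1 of them was lower. Of seed storage loci, a sign of grain remains, 1 was tested and was higher by 0.96 ± 0.09 (SE, n = 3 arrays), with its water channel well above background on 1 of 3 arrays. Without the filter on dim probes 7 seed storage loci were held, of which 2 were higher, with a median of -0.03.

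**Figure D2:**
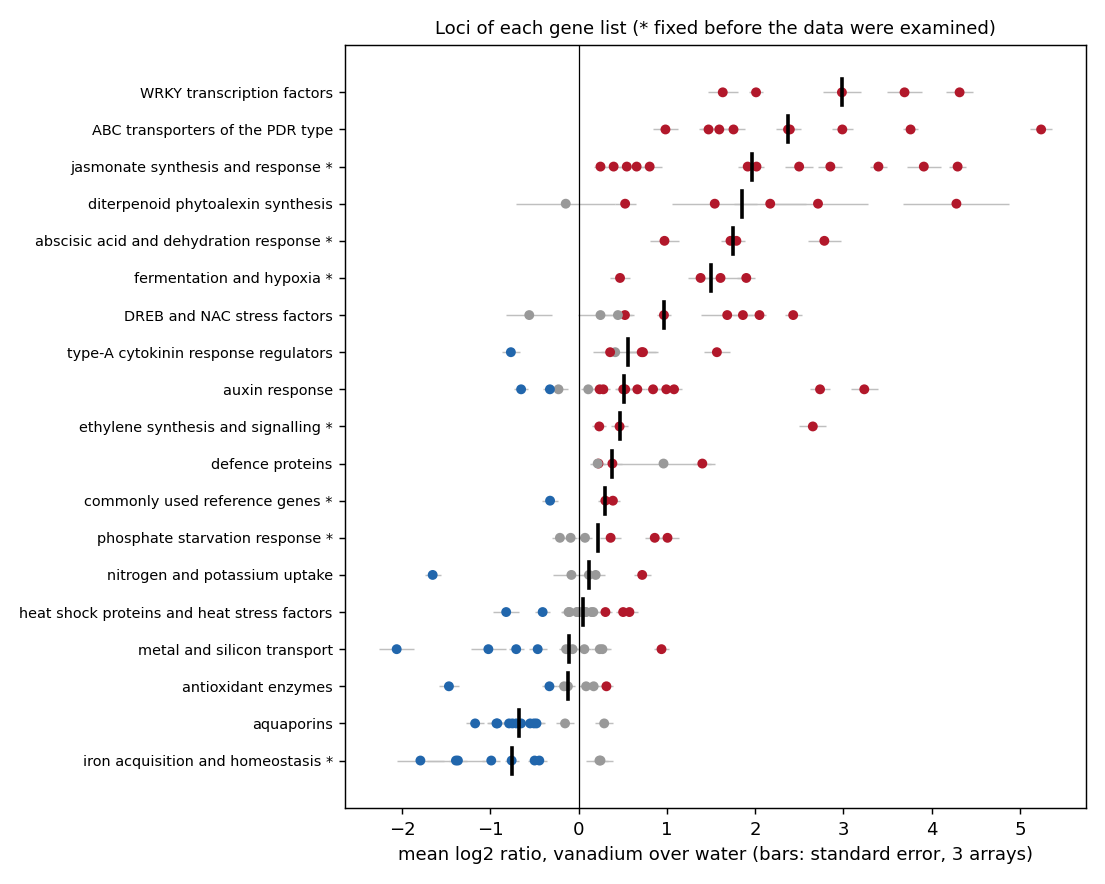
Mean log2 ratio of vanadium over water (horizontal axis) of each tested locus, grouped by gene list, with limma's moderated standard error from 3 arrays (grey bars) and list medians (black marks). Red points were higher, blue points lower and grey points not past the threshold, and an asterisk marks lists fixed before the data were examined. All 12 jasmonate loci lie right of 0, and 7 of 9 iron loci are lower.

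The treated and control RNA of a replicate shared an array. Fitting the 6 channels without this pairing called 3389 loci higher and 1490 lower, and 2108 changed at least 2-fold. Slide as a block gave 6609 higher and 4935 lower loci, and replicates 2 and 3, which shared a slide, gave 5668 and 3598 by themselves. The other slide held 1 array and allows no test of its own. Without replicate 3, 2908 loci were lower.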

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

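The tests of this part were written down before their results were seen, apart from the ratios and shifts with the scanner software's log ratio and the shift with an offset of 0, which were chosen afterwards. No group was large enough to test single arrays as outliers, since it held 3, and no pair of groups shared a contrast.

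Probes named after miRNAs in the array files stood outside the comparison of loci, and 42 of 163 such probes above background were higher under vanadium than in the water control, while 40 were lower (limma, adjusted over these probes). At least 2-fold higher were the 3'seq probe of osa-miR416, with a log2 ratio of 1.18 ± 0.13 (SE, n = 3 arrays), and the 5'seq probe of osa-miR399d, with 1.06 ± 0.16. These names were chosen after their values were seen. For the latter the water channel was not well above background on any array, and its call was lost without replicate 1 (0.93, adjusted p = 0.0528) and without replicate 2 (0.94, adjusted p = 0.0707). Without the pairing of channels the osa-miR416 probe had adjusted p = 0.0621.

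Far more loci rose than fell by 2-fold or more, 1870 against 333. With an offset of 0 and only probes well above background in both channels, 1516 rose and 432 fell, a ratio of 3.51 (3.06 to 3.95 leaving out an array), which argues against the background offset alone as the whole cause. A constant error of centring would need a shift of 0.400 on the log2 scale (0.378 to 0.408 leaving out an array) to level the counts, more than the bound of 0.3 set beforehand, while with an offset of 0 and both channels above background the shift was 0.299. With the scanner software's log ratio over all tested loci, the ratio was 2.21 against 5.62 here, and the shift 0.231. With that log ratio and both channels above background, 1448 rose and 905 fell, a ratio of 1.60 (1.43 to 1.72 leaving out an array) with a shift of 0.113 (0.089 to 0.131). Offset, dim probes and centring acting together are therefore not excluded, and the size of the excess depends on the processing. With 0 arrays of swapped dyes, a gene-specific dye effect and a response to vanadium cannot be told apart.

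Risen loci stood next to each other in locus number more often than by chance. Among 641 loci that rose 4-fold or more, 67 adjacent pairs both rose, against a median of 19 and a highest value of 33 in 1000 shuffles, which argues against chance placement. Spots next to each other on the array had uncorrelated ratios (-0.00237 across 74907 pairs of spots), which argues against position on the array. The files used here held 0 columns of probe sequence, so cross-hybridisation between tandem copies and joint regulation of neighbours cannot be told apart.

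The 3 arrays allow 4 assignments of sign, too few for a share under 0.05. The real one called 10766 loci in 1 of 4 assignments, and the highest of the others called 0.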

How the results depend on the processing

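Tests chosen after the data were seen were slide as a block, spots marked as outliers kept, and lists restricted to loci that passed the order check. The cause of each change below was not tested. An offset of 0 gave 509 loci at least 2-fold lower. Median centring gave 4142 higher loci. The scanner log ratio gave 6882 lower loci, 3565 changed and 1111 lower at least 2-fold, and turned the share of changed loci that were higher to 41.5%. The authors' deposited value table gave 7004, 3597 and 1117, and 41.5%. Without the pairing of channels on an array (no replicate block), 3389 were higher and 1490 lower, and 69.5% of changed loci were higher. At an adjusted p under 0.01, 2322 were lower. Leaving out each array gave 2908 to 3598 lower loci. Lists called among those fixed beforehand numbered 2, but 1 on probes above background in both channels, 1 over order-checked loci, and 0 with an estimated correlation, which also left 0 of 5 called lists of those added. The other totals of changed loci and of called lists stayed within 1.5 times of their value, while counts within single lists could move further. Of 205 values for the 4 loci and the 9 miRNA probes named for a change of 2-fold or more, 201 kept direction and side of the threshold and 4 lost the call. On probes well above background in both channels only 10 of these 13 had a value, and those that dropped out are not counted. All 13 had been chosen as called with large changes, which favours a high share. Slide as a random block could not be fitted, since the within-slide correlation could be estimated for 0 loci. Dim signal limited 500 tested loci whose water channel was above background on no array, and 53 whose vanadium channel was above background on no array. A difference between the dyes can contribute to the gap between these counts.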

Other observations

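The array files name some probes after miRNAs, as mature, 5'seq or 3'seq probes, and the largest falls among them included 2 pairs from the same miRNA. The names below were chosen after their values were seen. The 5'seq and 3'seq probes of osa-miR171f both fell, with log2 ratios of -1.75 ± 0.07 and -1.54 ± 0.12 (SE, n = 3 arrays). Those of osa-miR159a fell as well, with -1.16 ± 0.10 and -1.33 ± 0.08. The 5'seq probe of osa-miR171h had -1.20 ± 0.07, while the mature probe of osa-miR171h was not called (0.13 ± 0.26, adjusted p = 0.641), with -0.13, 0.97 and -0.45 on replicates 1, 2 and 3. The 3'seq probe of osa-miR169i had -1.05 ± 0.12, a size that rests on a dim signal, since its vanadium channel was well above background on 1 of 3 arrays. The 3'seq probe of osa-miR166a had log2 ratios of -0.60, -1.26 and -1.15 on replicates 1, 2 and 3. All 7 probes that fell had the same sign on all 3 arrays, with adjusted p between 0.000105 and 0.00237 (limma). Without the pairing of channels the osa-miR169i probe lost its call (adjusted p = 0.360). These probes were read from cRNA amplified from total RNA, and whether they follow mature miRNA was not tested.

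Of the 58 runs of adjacent loci that rose 4-fold or more, 8 held at least 3 loci, 25 loci in all, and the longest held 4. Log2 ratios of adjacent loci correlated at 0.117 across 21083 pairs.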
